A study of Rattus norvegicus with 15 samples.

How the data were processed

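RNA of 5 states of rat vessel was measured on 3 Affymetrix chip types (A, B and C), 1 array per state and chip type, 15 arrays in all. The states were fetal ductus arteriosus and fetal aorta (day 19), newborn ductus and newborn aorta (3 h after vaginal delivery), and ductus of fetuses whose dams had breathed 100% oxygen for 3 h. Per the labels, vessels were cleaned of adhering tissue and dissected in medium with 2.5% oxygen for fetuses and 12.5% for newborns. The title of the newborn aorta array of chip A counts its 3 h from coitum while its description says newborn, and it was taken as newborn. Descriptions for chips B and C cover all states together, so their states come from the titles and their details from chip A. The labels do not say how many animals an array represents. The deposited values were linear signal intensities, and the submitters' notes name MAS5 for 4 of the 5 arrays of chip A (not for the fetal aorta) and no software for chips B and C. The mean of each deposited array after trimming 2% at each end was 500 to 501, so the arrays had been scaled to a common mean before deposit, and further scaling to a common trimmed mean moved no array beyond factors of 0.99992 to 1.0001.

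Control probe sets were left out, which left 26202 probe sets, 18178 of them assigned to 1 gene, 391 to several and 7633 to none. Of those assigned to 1 gene, 18122 were found by gene number in a current rat gene table, 56 were not, and 0 symbols changed. Signals under the pooled median of the chip (149.79, 241.69 and 243.01 on A, B and C) were set to that floor before log2 was taken, and a fold with 1 side at the floor is given as a lower bound. A gene was read at its brightest probe set.

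Choices of comparison, setting, gene list and named gene were made before the data were examined, except where the text says otherwise. The 6 comparisons of state pairs (ductus against aorta in fetus and newborn, newborn against fetus in each vessel, oxygen against fetal ductus, newborn against oxygen ductus) had 1 array per side, so no test was made. Probe sets at least 2-fold higher or lower were counted among those above the floor on at least 1 of the 2 arrays. Comparisons that share an array are linked by construction. Vessel and birth effects were also fitted per chip with limma (version 3.58.1, R 4.3.3) as an additive model of vessel and stage on 4 arrays, for probe sets above the floor on at least 2 of them. The residual degree of freedom was 1, so the interaction of vessel and stage served as error, prior degrees of freedom were 6.62, 9.70 and 5.94 on A, B and C, and Benjamini-Hochberg adjusted p under 0.05 was the threshold per chip. Probe sets 2-fold apart numbered 107 for the vessel contrast, 352 for birth and 57 for the interaction contrast, scaled to the same variance. The estimated standard deviation of a log2 ratio of an unchanged gene, taken from that interaction by signal bin, was 0.20 to 0.35 with a median of 0.31.

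For 20 gene lists (contractile smooth muscle, heart or skeletal muscle, endothelium, matrix, prostaglandin, vasoactive and nitric oxide signalling, channels, immediate early, glucocorticoid-responsive, hypoxia and glycolysis, antioxidant, cell cycle, fatty acid, inflammatory, leukocyte, erythroid, nerve and chromaffin, fat, epithelium with airway and cartilage, growth factor with Notch) the median log2 ratio of the measured members was set against 10000 random lists matched on chip and signal decile, which makes 120 comparisons. Further lists of sterol synthesis, circadian clock, heart muscle and skeletal muscle genes were added after the data were seen. The genes named per pair were the 10 with the largest fold each way among genes with both arrays above the floor, the brighter at or above the 75th percentile of its chip, and all measured probe sets going the same way, with up to 5 each way whose dimmer array was at the floor. For the fits the 10 largest effects each way past the threshold were named among genes read at their brightest probe set whose measured probe sets all went the same way, for states the 5 largest, for oxygen and birth the 10 each way with the largest smaller fold, for lists the 2 to 4 members with the largest change in the direction of the median, and 11 genes usual in ductus work whatever they showed. Genes set beside these to contrast comparisons were chosen after their values were seen.

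The limma fit was tried on simulated data with the same states and filters. Noise was normal, with a single size per chip and no interaction of vessel and stage. Changed probe sets were drawn from those with a mean signal more than 2-fold above the floor. The fit recovered 93 of 100 probe sets with a 2-fold and 100 of 100 with a 4-fold birth change (median estimates 1.01 and 1.96). It called 11 of 13291 unchanged ones for birth and 0 for vessel. Noise of the measured arrays varied with signal, so these rates may be better than those of the measured data. Of 50 random lists of 20 genes, 4% lay outside the 95% range unshifted and 100% after a shift of 0.5. Alternatives were quantile normalization, the deposited values without scaling, floors at the 25th and 65th percentile, an intensity trend in the variance, the oxygen ductus added as a fetal ductus array, and the mean over the probe sets of a gene. The 6 control probe sets present on all chips gave ratios with a spread across chips of 0.083 to 0.142 (log2). Other work used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.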

Results

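Gene expression was measured in 2 great vessels of the rat around birth, the ductus arteriosus, which joins the pulmonary artery to the aorta in the fetus and closes after birth, and the aorta (arch and thoracic part). There were 5 states: ductus and aorta of fetuses at day 19 of gestation, ductus and aorta of newborns 3 h after vaginal delivery, and ductus of day 19 fetuses whose dams had breathed 100% oxygen for 3 h before caesarean section (the oxygen ductus). Each state was hybridised once to each of 3 Affymetrix rat chip types (A, B and C), 15 arrays in all, which together carried 26202 probe sets other than controls and 10969 named genes. With 1 array per state and chip type no state had replicates, so ratios between 2 states compare 2 arrays, and their number limits the precision. Values are signal intensities, and a signal under the floor, the pooled median of its chip (150 on chip A, 242 on chip B and 243 on chip C), was set to the floor, which makes folds against it lower bounds. Between 46.9% and 51.9% of the probe sets of an array lay above the floor. An unchanged gene was estimated to give a log2 ratio with a standard deviation of 0.20 to 0.35, depending on chip and signal, and simulated unchanged arrays gave about 19 probe sets at least 2-fold apart in a pair. The simulated noise was normal and leaves out rarer large errors. The number for measured unchanged arrays may thus be higher, and it was not measured, for want of replicates. A gene list is called higher or lower where its median log2 ratio lay outside the 95% random range. That range comes from 10000 random lists matched on chip and signal, and leaves about 1 in 20 lists of unrelated genes outside. Genes of a real list may vary together between samples, so their rate may be higher, and it was not tested.

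The fetal ductus was set against the fetal aorta to find what marks the ductus before birth. Contractile smooth muscle genes were higher in the ductus, with a median log2 ratio of 0.62 over 19 measured genes, 10 of them at least 1.5-fold higher and 0 at least 1.5-fold lower. Des (desmin, an intermediate filament of muscle) was 2.62-fold higher, Synpo2 2.37-fold, Actg2 (gamma smooth muscle actin) 2.06-fold and Vcl (vinculin) 1.92-fold. Myh11, the smooth muscle myosin heavy chain, had a log2 ratio of 0.68 and Acta2 (smooth muscle alpha-actin) one of 0.33. Rgs5, a regulator of G protein signalling of pericytes and arterial smooth muscle, was 4.65-fold higher, at a signal of 9334 against 2009. The combined list of heart and skeletal muscle was also higher (median 0.67, 14 of 24 genes at least 1.5-fold higher and 2 lower), and when it was split after its values were seen, heart genes were at 1.06 (14 genes) and skeletal genes lower, at -0.47 (6 genes). It was led by the myosin light chain Myl2 (6.93-fold) and by Nppa, the atrial natriuretic peptide precursor (at least 4.21-fold). Myh7 was 2.97-fold higher, Tnnt2 2.94-fold and Myh6 2.88-fold, all genes of the heart muscle sarcomere.

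Channels and pumps for potassium and calcium had a median log2 ratio of 0.18 over 19 genes (5 at least 1.5-fold higher and 2 lower), above the random range, although this median was -0.09 with a lower floor. Its largest members were Cacna2d1, a calcium channel subunit (2.99-fold), Kcnk3, a background potassium channel (2.38-fold), the sarcoplasmic calcium pump Atp2a2 (2.05-fold) and the sodium-calcium exchanger Slc8a1 (1.89-fold). Other genes higher in the fetal ductus were Popdc2 (3.47-fold), Fabp3 (3.33-fold), Pdlim3 (3.23-fold), Atp1b1 (2.95-fold), Jph2 (at least 5.64-fold), Ceacam12 (at least 4.79-fold), Nos2 (at least 3.79-fold) and Myl3 (at least 3.36-fold). Whether any of these, or of the channels and pumps, share a source with the higher heart muscle genes of this sample was not tested. For Jph2, Ceacam12 and Nos2 the fetal aorta was the single state of the 5 under the floor. Genes of epithelium, airway and cartilage had a median of 0.14 (14 genes, 6 at least 1.5-fold higher and 2 lower), led by Col9a1 (2.84-fold) and Col2a1 (2.07-fold), and this call was lost with a higher floor, at -0.02.

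Lower in the fetal ductus than in the fetal aorta were the calmodulin-binding gene Pcp4 (5.40-fold), Gas2 (4.21-fold), the angiotensin receptor Agtr2 (4.09-fold), the mast cell protease Cma1 (3.42-fold), the collagen Col8a1 (3.30-fold), Efemp1 (3.28-fold) and the prostacyclin receptor Ptgir (3.17-fold), besides Adipor2 (3.01-fold) and Sult1a1 (2.94-fold). Bounds were reached by Nptx2 (at least 3.96-fold lower), Aaas (at least 3.77-fold), the glucocorticoid-activating enzyme Hsd11b1 (at least 3.60-fold) and Alb (at least 3.32-fold). The prostaglandin list had a median of -0.26 (11 genes, 3 at least 1.5-fold lower and 2 higher), with Ptgfr 1.76-fold lower next to Ptgir, and Slco2a1 and Ptgis, the prostaglandin transporter and prostacyclin synthase, 1.76-fold and 1.54-fold higher. Erythroid genes (median -0.80, 12 genes), nerve and chromaffin genes (-0.60, 18 genes) and leukocyte genes (-0.43, 19 genes) were lower too. Examples were Ahsp, the alpha-haemoglobin stabilising protein (3.92-fold), Th, tyrosine hydroxylase (2.53-fold), Prph (2.01-fold) and the complement gene C1qb (2.68-fold). Matrix (-0.06), endothelial (-0.19), vasoactive (0.04), immediate early (0.10), glucocorticoid-responsive (0.02), hypoxia and glycolysis (0.05), antioxidant (0.01), cell cycle (0.06), fatty acid (0.05), inflammatory (-0.10), fat (-0.13) and growth factor (0.00) lists stayed inside the random range. In total 143 probe sets were at least 2-fold higher and 130 at least 2-fold lower among 14236 compared. Where a probe set was at least 2-fold apart and its gene had others, 86.7% of these (225 ordered pairs) went the same way, against 49.5% for random partners.

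After birth smooth muscle genes again had higher signals in the ductus than in the aorta. The aorta samples were higher in other lists, fat genes in the newborn (-1.98 for ductus over aorta) and erythroid (-0.80), nerve (-0.60) and leukocyte genes (-0.43) in the fetus. How far such differences in tissue content enter the smooth muscle ratios of arrays scaled to a common mean was not tested. The smooth muscle median was 0.42 (19 genes, 8 at least 1.5-fold higher and 0 lower), with Actg2 2.42-fold, Synpo2 2.40-fold, Itga8 2.24-fold and Myh11 2.00-fold higher, and Acta2 at a log2 ratio of 0.42. The channel list was higher as well (median 0.40, 17 genes). Abcc9 (3.17-fold) and Kcnj8 (2.38-fold), the 2 subunits of the vascular ATP-sensitive potassium channel, led it together with Kcnk3 (2.27-fold) and the voltage-gated potassium channel Kcna5 (at least 2.23-fold, since its newborn aorta signal of 79.0 was under the floor). Further genes higher in the newborn ductus were Tgfbi (3.88-fold), the neuropeptide gene Gal (3.77-fold), the metalloprotease Adamts1 (3.41-fold), the glucocorticoid-inducible Fkbp5 (3.15-fold), Clic2 (3.12-fold), Slc44a2 (3.06-fold), Sorbs2 (3.05-fold), Mcam (2.88-fold) and Fam168a (2.86-fold). Bounds were met by Dysf (at least 4.54-fold), Satb1 (at least 2.84-fold) and Phf1 (at least 2.69-fold), and Dysf was under the floor in the newborn aorta alone. Growth factor and ductus development genes had a median of 0.22 (33 genes, 4 at least 1.5-fold higher and 2 lower), with Igfbp4 2.04-fold and Inhba 1.90-fold higher, and immediate early genes one of 0.26 (28 genes), a call that was lost when all probe sets of a gene were averaged.

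Fat genes were far lower in the newborn ductus than in the newborn aorta, with a median log2 ratio of -1.98 over 10 genes, 8 of them at least 1.5-fold lower. The fatty acid binding protein Fabp4 was 12.0-fold lower, Ucp1, the uncoupling protein of brown fat, at least 5.85-fold, Pparg at least 5.56-fold and Adipoq (adiponectin) at least 4.42-fold. Genes of fatty acid oxidation and uptake were lower alongside (-0.48, 22 genes, 8 at least 1.5-fold lower), among them Acsl1 (3.69-fold) and Lpl (3.33-fold). The other large differences in that direction were Car3 (15.6-fold), Gpd1 (at least 13.4-fold), Pck1 (at least 7.53-fold), Chchd10 (7.24-fold), Mgst1 (5.76-fold), Dgat2 (5.07-fold), Msln (4.41-fold), Pcp4 (4.35-fold), Psat1 (3.77-fold) and Cidea (3.54-fold). The combined heart and skeletal muscle list was lower in the newborn ductus (-0.47, 21 genes), with heart genes at -0.72 and skeletal genes at 0.00, including Myl7 (2.46-fold) and Tnnt2 (2.09-fold). Leukocyte (0.10), erythroid (0.02), nerve (0.10), endothelial (-0.12), matrix (0.08), prostaglandin (-0.01), vasoactive (0.09), glucocorticoid (0.15), hypoxia (-0.06), antioxidant (-0.08), cell cycle (-0.11), inflammatory (0.15) and epithelial (0.06) lists were inside the random range. Counts were 178 probe sets at least 2-fold higher and 180 lower among 14179, and 78.6% of the same-gene partners of these went the same way.

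Across both stages, limma called 5 of 13811 probe sets different between ductus and aorta, 2 higher and 3 lower in the ductus. The single named gene among them, Pcp4, was lower in the ductus at both stages, by a log2 effect of -2.28 (SE 0.20, limma adjusted p = 0.022). None of the smooth muscle genes passed limma over all probe sets, although all 19 had positive effects and 9 passed when adjusted over the list alone, Actg2, Myh11, Tagln, Mylk, Tpm2, Des, Vcl, Synpo2 and Itga8. Adjusted over their lists alone, the other members that passed as higher in the ductus were Kcnk3, Abcc9, Cacna2d1, Edn1, Thbd, Tnc, Rgs5, Errfi1, Nppa and Acan, and those that passed as lower were Ptgir, Col6a1, Col8a1, Spp1, Agtr2, Tnnc2 and Dgat2. At an unadjusted p under 0.05 there were 1071 probe sets (7.75%). The ratios of the 2 stages correlated across probe sets with r = 0.13, and 32 probe sets were at least 2-fold higher in the ductus at both stages against 1.68 for independent lists, 12 lower at both, against 1.54, and 10 in opposite directions. Of the 577 at least 2-fold apart at either stage, 54.1% had the same sign at the other. The 4 arrays left 1 residual degree of freedom, with the vessel-by-stage contrast as error, and the limma count ran from 0 with a lower floor to 64 with an intensity trend.

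**Figure D1:**
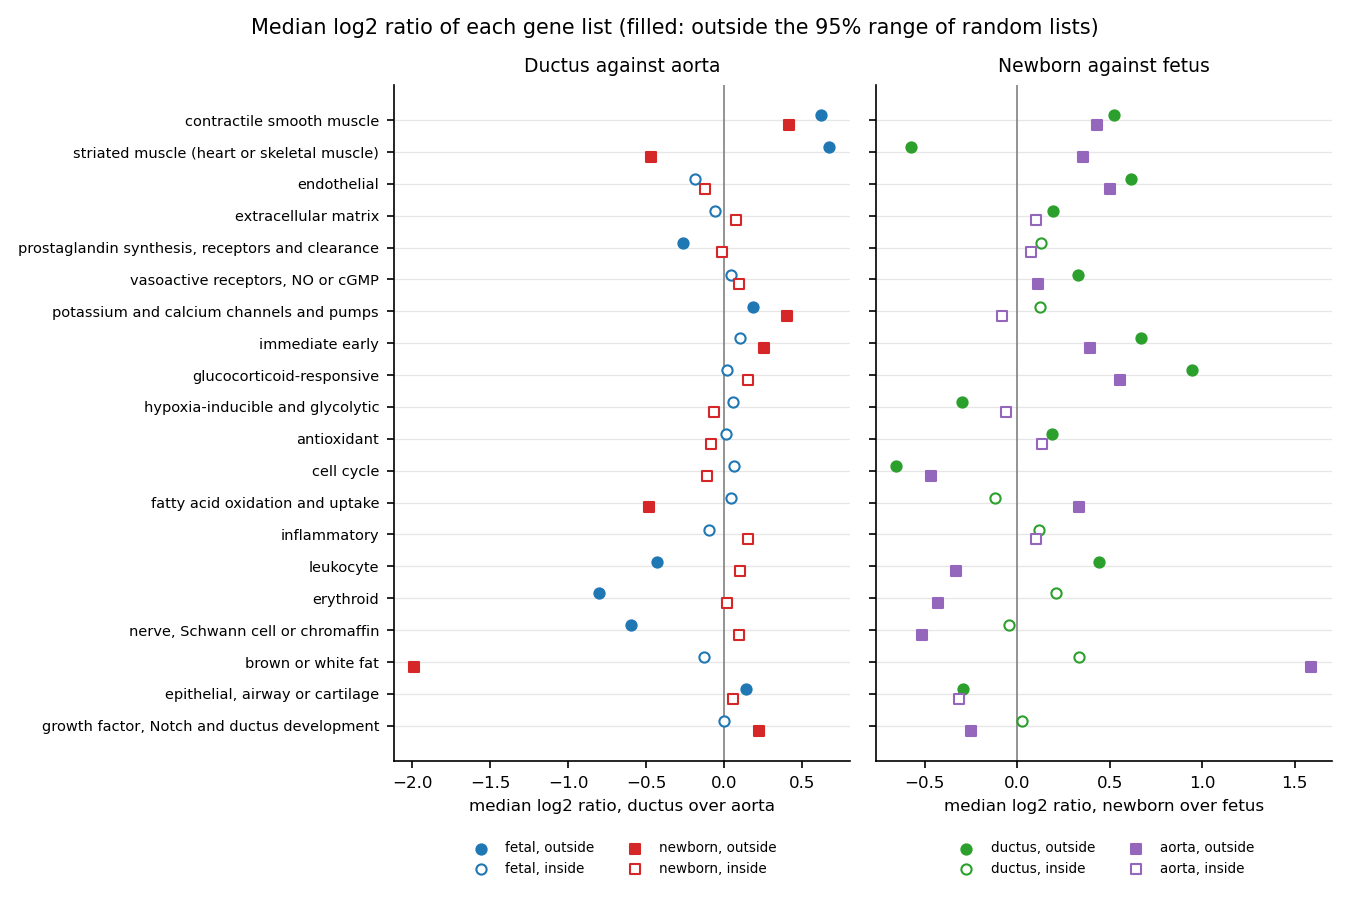
Median log2 ratio (x axis) of the measured genes of each of the 20 gene lists (y axis), ductus over aorta on the left and newborn over fetus on the right, 1 array per state, with symbols filled outside the 95% range of 10000 matched random lists. Smooth muscle medians lie between 0.42 and 0.62 in all 4 comparisons, and the fat list reaches -1.98 and 1.59 in the comparisons that hold the newborn aorta.

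Birth was followed first in the ductus, as newborn against fetal ductus. Closure of the vessel was not measured, so these ratios cannot be tied to it. Glucocorticoid-responsive genes were higher in the newborn ductus (median log2 ratio 0.95, 15 genes, 10 at least 1.5-fold higher and 0 lower), among them Fkbp5 (3.68-fold), Glul, glutamine synthetase (3.65-fold), Pdk4 (at least 3.16-fold) and Errfi1 (2.96-fold). Immediate early genes followed with a median of 0.67 (28 genes, 15 at least 1.5-fold higher and 1 lower), led by the transcription factor genes Klf9 (4.92-fold), Atf3 (3.33-fold), Klf2 (2.78-fold) and Klf4 (2.59-fold). Endothelial genes had a median of 0.61 (14 genes), with Selp, P-selectin, and Ace, angiotensin-converting enzyme, each 1.92-fold higher and Edn1, the endothelin-1 precursor, 1.63-fold. Smooth muscle genes had a median of 0.53 (19 genes), with Des 3.42-fold, Itga8 2.75-fold, Synpo2 2.03-fold and Tpm2 1.86-fold higher. Myh11 and Acta2 each had a log2 ratio of 0.59.

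Vasoactive genes were higher in the newborn ductus as a group (0.33, 24 genes), including Rgs5 (2.25-fold), the angiotensin receptor Agtr1a (2.05-fold), Rock2 (1.97-fold) and Rhob (1.96-fold). Matrix genes were higher by a smaller amount (0.19, 35 genes), with Col14a1 2.98-fold and Spp1 1.82-fold higher and elastin (Eln) at a log2 ratio of 0.08. The antioxidant median was 0.19 (27 genes), with Sod3 2.09-fold and Gpx4 1.89-fold higher, a call lost when probe sets were averaged. Leukocyte genes were higher (0.44, 21 genes), with Lyz2 1.77-fold and the T cell receptor subunit Cd3e 1.73-fold. Among single genes, Alox15, a lipoxygenase, was 5.70-fold higher, Bnip3 4.31-fold, Lmcd1 4.19-fold, the class I gene RT1-A1 3.89-fold, Isca1 3.65-fold, Nupr1 3.62-fold and Rnase4 3.55-fold. Nptx2 was at least 6.40-fold, Pla2g2a at least 4.04-fold, Rsad2 at least 3.79-fold, Hip1r at least 3.69-fold and Aaas at least 3.47-fold higher. Nptx2 and Aaas were also under the floor in the fetal ductus when set against the fetal aorta, so the 2 comparisons share that array, and so does the comparison with the oxygen ductus.

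Cell cycle genes were lower in the newborn ductus (median -0.65, 30 genes, 16 at least 1.5-fold lower and 0 higher), for example Cdc20 (2.76-fold), Ccna2 (at least 2.72-fold), the proliferation marker Mki67 (2.43-fold) and the replication helicase gene Mcm5 (2.32-fold). Hypoxia-inducible and glycolytic genes were lower too (-0.30, 23 genes), with Pfkm 1.80-fold and Epas1 1.56-fold lower, while Bnip3 of the same list went the other way. The combined heart and skeletal muscle list was lower (-0.58, 24 genes, 12 at least 1.5-fold lower), with heart genes at -1.14 and skeletal genes, inside the random range, at -0.12. Among its lower members were Myl2 (5.68-fold), Tnnt2 (4.23-fold), Myl7 (3.76-fold), Tnni1 (3.69-fold), Myh7 (3.46-fold), Myh6 (3.09-fold), Actc1 (3.02-fold) and Myl3 (at least 3.36-fold). The embryonic globin Hbe1 was 25.9-fold lower, Hbz at least 2.98-fold, Wdr24 3.09-fold and Skp2 3.07-fold. Epithelial and cartilage genes were lower (-0.29, 14 genes), with Col9a1 2.69-fold lower. The erythroid median (0.21) and its mean (-0.09) differed in sign, and this list, prostaglandin (0.13), channel (0.13), fatty acid (-0.12), inflammatory (0.12), nerve (-0.05), fat (0.33) and growth factor (0.03) genes stayed inside the random range. Counts were 292 probe sets at least 2-fold higher and 268 lower among 14208, and 83.9% of the same-gene partners of these went the same way.

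Several genes often studied in the ductus were followed by name, and some of them lay near the floor. The prostaglandin E receptor Ptger4 had signals of 145 in the fetal and 120 in the newborn ductus, under the floor, against 83.2 and 166 in the fetal and newborn aorta. Ptgs1, cyclooxygenase 1, had a log2 ratio of 0.96 with birth in the ductus and 0.51 in the aorta, whereas Ptgs2 passed the floor in the newborn ductus alone (162). Edn1 had ductus-over-aorta ratios of 0.68 in the fetus and 0.76 in the newborn. Agtr2 was lower in the ductus at both stages, with log2 ratios of -2.03 and -0.63, and Kcna5 was at -0.06 in the fetus. The Notch ligand Jag1 had a ratio of 0.62 in the fetus and -0.01 in the newborn, and of -0.91 with birth in the ductus and -0.28 in the aorta. Eln was nearly equal in the vessels, with 0.00 in the fetus and -0.09 in the newborn. The endothelin receptor Ednra had no probe set assigned to it alone.

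**Figure D2:**
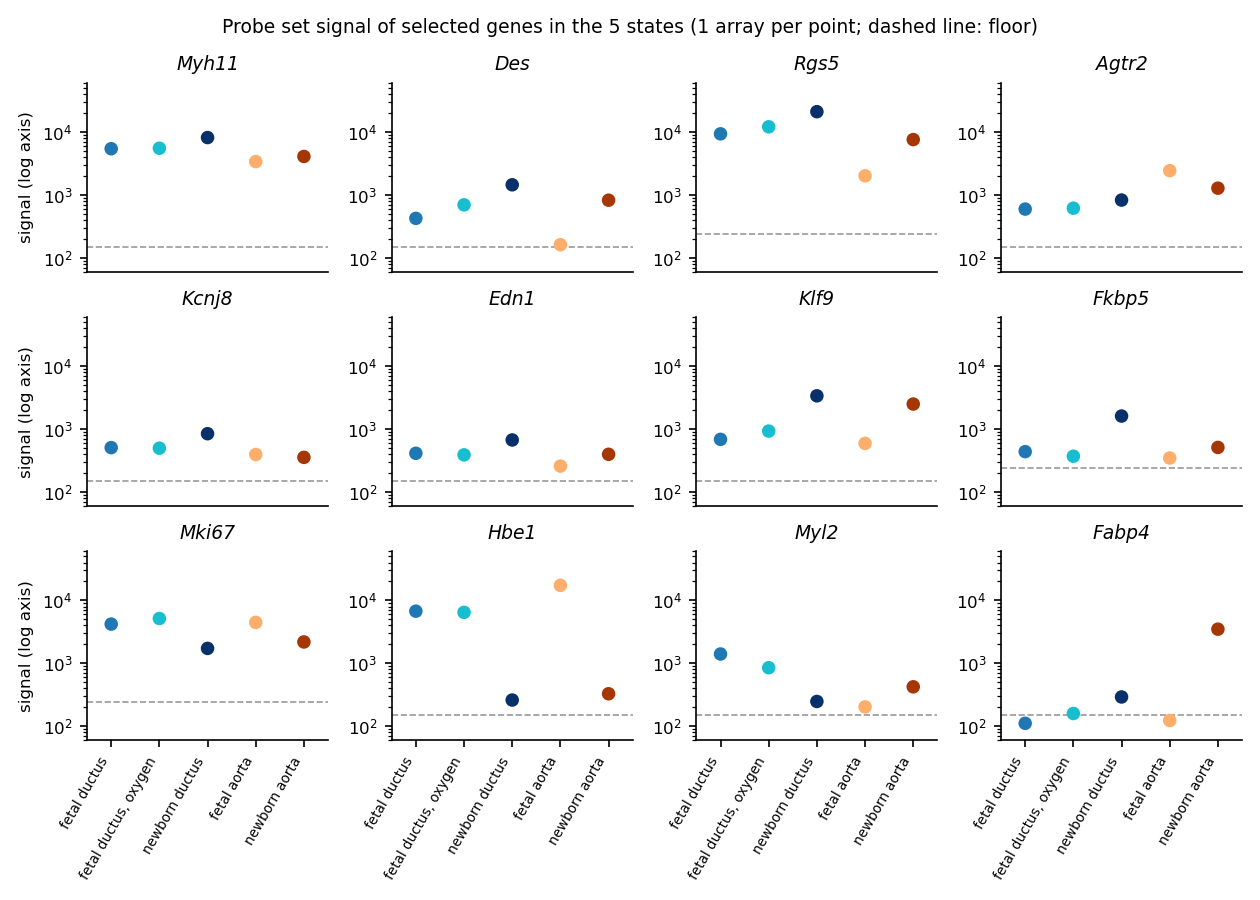
Probe set signal (y axis, log scale, arbitrary intensity units) of 12 genes in the 5 states (x axis), 1 array per point, with the floor of the chip as a dashed line. Klf9 and Des are higher in both newborn vessels, Hbe1 falls from 6741 and 17356 in the fetal vessels to 261 and 328 in the newborn ones, Myl2 is highest in the fetal ductus and Fabp4 in the newborn aorta.

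In the aorta, newborn against fetal, fat genes were higher, and whether they come from the vessel or from fat on the sample was left open. Their median was 1.59 (11 genes, 8 at least 1.5-fold higher), with Fabp4 at least 23.3-fold, Cidea 8.26-fold, Ucp1 at least 5.85-fold and Pparg at least 5.56-fold higher. Fatty acid oxidation and uptake genes had a median of 0.34 (22 genes), with Acsl1 5.39-fold, Lpl 4.42-fold and Acadm 2.26-fold higher. Glucocorticoid-responsive genes were higher (0.56, 17 genes), including Cebpb (3.38-fold), Glul (2.22-fold) and Pck1 (at least 7.53-fold, in the array with the fat genes). Immediate early genes were higher (0.39, 29 genes), with Klf9 4.22-fold and Atf3 3.46-fold. Endothelial genes were at 0.50 (15 genes), with Thbd, thrombomodulin, 2.61-fold, Tie1 2.02-fold and Tek 1.97-fold higher. Smooth muscle genes were at 0.43 (19 genes), with Des 5.10-fold and Synpo2 2.00-fold higher. The combined heart and skeletal muscle list was at 0.35 (20 genes), with heart genes at 0.58, skeletal genes at -0.18 inside the random range, Tnni3 2.18-fold and Myl2 2.09-fold higher. The vasoactive median of 0.12 (26 genes, 5 at least 1.5-fold higher and 4 lower) was above the random range, a call lost with either other floor, and it went to -0.01 with the lower.

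Single genes with the largest higher ratios in the newborn aorta were Car3 (24.9-fold), Lmcd1 (6.91-fold), Chchd10 (5.59-fold), Nupr1 (5.22-fold), Mgst1 (5.17-fold), Pla2g2a (4.83-fold), the complement factor Cfb (4.77-fold), Gpd1 (at least 13.4-fold), Ceacam12 (at least 7.48-fold) and Jph2 (at least 6.72-fold). Lower were cell cycle genes (-0.47, 31 genes, 11 at least 1.5-fold lower and 0 higher), such as Plk1 (2.32-fold) and Mki67 (2.05-fold), and erythroid genes (-0.43, 12 genes), with Hbe1 52.9-fold and Hbz at least 8.22-fold. Nerve and chromaffin genes were lower (-0.51, 18 genes, 8 at least 1.5-fold lower and 2 higher), with Prph at least 3.54-fold, Stmn2 at least 3.03-fold and Th 2.89-fold. Leukocyte genes were at -0.33 (19 genes, 8 at least 1.5-fold lower and 2 higher), with C1qb 2.16-fold lower, a call lost with either other floor and when probe sets were averaged. Growth factor genes were at -0.25 (32 genes, 6 at least 1.5-fold lower and 4 higher), with Igf1 3.09-fold and Pdgfra 2.06-fold lower, a call lost with a lower floor. Other lower genes were Scarb1 (5.89-fold), Gas2 (5.48-fold), Ncapd2 (4.24-fold), Rtn1 (3.90-fold), Marcks (3.60-fold), Acat2 (3.31-fold), Tubb2b (3.30-fold), Nrk (3.18-fold), Sqle (3.12-fold), Afp (at least 6.24-fold), Dysf (at least 4.83-fold) and Skp2 (at least 3.94-fold). Matrix (0.10), prostaglandin (0.08), channel (-0.08), hypoxia (-0.06), antioxidant (0.14), inflammatory (0.10) and epithelial (-0.32) lists stayed inside the random range. Counts were 363 probe sets at least 2-fold higher and 360 lower among 14444, and 87.2% of the same-gene partners of these went the same way.

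Over both vessels together, 132 probe sets rose and 96 fell with birth by limma among 13811 tested, covering 146 named genes. In this fit the vessels acted as the replicates of each stage. Its adjusted p thus measures agreement of the vessels, and not variation between animals or litters. Among genes read at their brightest probe set and with all measured probe sets going the same way, the largest rises were those of Lmcd1 (log2 effect 2.43, SE 0.22, limma adjusted p = 0.031) and Klf9 (2.19, SE 0.20, limma adjusted p = 0.0063), followed by Alox15 (2.18), Pla2g2a (2.14), Nupr1 (2.12), Des (2.06), Bnip3 (1.78), Atf3 (1.76), Ltbp2 (1.71) and Hip1r (1.66). Of these genes Hbe1 fell most (-5.21, SE 0.27, limma adjusted p = 0.00042), and the yolk sac and liver gene Afp (-1.96) and the embryonic globin Hbz (-2.31) fell with it. Also falling were Skp2 (-1.80), which drives cells into S phase, Bud23 (-1.55), Rtn1 (-1.54), the sterol synthesis genes Sqle (-1.53) and Msmo1 (-1.51), Cdkn1c (-1.50) and Crabp2 (-1.47). Each of these genes moved the same way in both vessels, which passing this fit largely requires. The effects of Hbz and Bud23 rest on both newborn arrays, those of Afp and Skp2 on the newborn aorta array and those of Pla2g2a and Hip1r on the fetal ductus array set to the floor, so their sizes and order depend on it. Of 28 immediate early genes tested, 5 rose (Junb, Egr1, Atf3, Nr4a1 and Klf9) and 10 rose when adjusted over the list alone. Of 29 cell cycle genes, 4 fell (Mki67, Mcm5, Mcm6 and Cdc20) and 15 fell over the list alone. Of 19 smooth muscle genes, 3 rose (Des, Synpo2 and Itga8), with 4 over the list alone, and of 16 glucocorticoid-responsive genes 2 rose (Cebpb and Glul), with 8 rising and 1 falling over the list alone. None of 14 endothelial genes passed over all probe sets, and 8 rose over the list alone, among them Pecam1, Tek, Edn1 and Ace. Other list members that rose were Rock2, Col14a1, Sod3, Lpl and Npy, and Igf1, Tnni1 and Cd74 fell. All these list counts read a gene at its brightest probe set, and dimmer probe sets of further members passed over all probe sets. Examples were those of Fos, Klf4, Dusp1, Nfkbia, Errfi1 and Myh11, which rose, and of Ccnd1 and Rrm2, which fell.

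The birth ratios of ductus and aorta, which share no array, correlated across probe sets with r = 0.42 (Spearman rho 0.38, 15164 probe sets, which are not independent replicates). There were 87 probe sets at least 2-fold higher in both vessels, against 6.99 for independent lists, 59 lower in both, against 6.36, and 3 in opposite directions. With a lower floor r was 0.29 and the counts 187 and 198, and with a higher one they were 58 and 33. Fetuses and newborns differed also in developmental age, route of delivery and the oxygen of the dissection medium (2.5% for fetuses and 12.5% for newborns, per the labels). At an unadjusted p under 0.05 limma gave 2575 probe sets, and the adjusted count was 0 with a lower floor and 3 with the oxygen ductus added as a fetal ductus array.

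**Figure D3:**
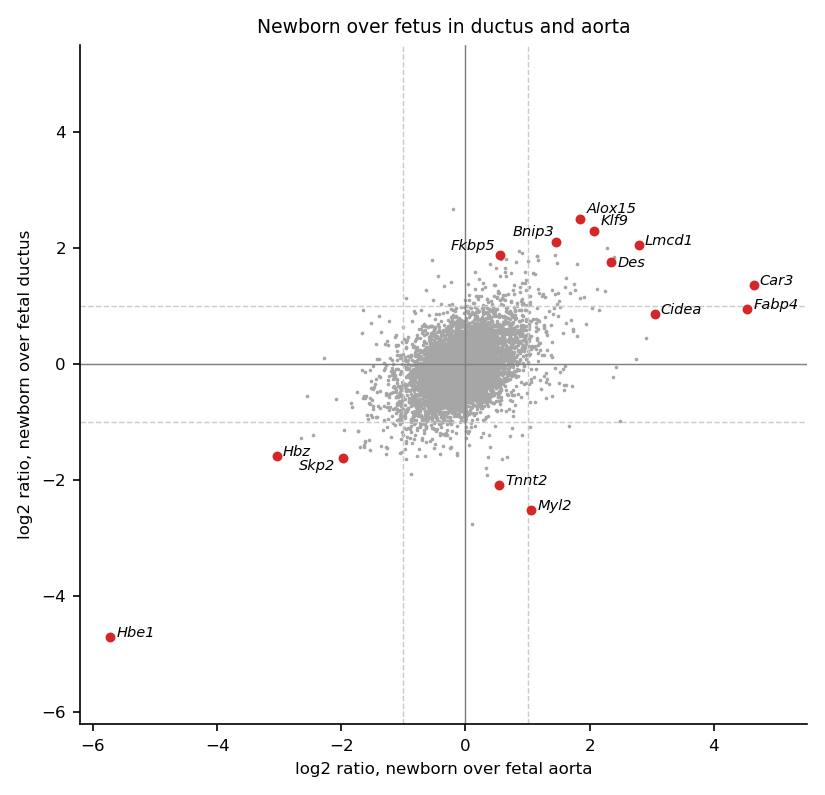
Log2 ratio of newborn over fetal ductus (y axis) against newborn over fetal aorta (x axis), each point 1 gene at its brightest probe set, 1 array per state, with dashed lines at 2-fold. Hbe1 lies at -4.69 and -5.73, Klf9 and Des are high in both vessels, Myl2 and Tnnt2 are low in the ductus alone, and Car3 and Fabp4 are highest in the aorta.

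Raised maternal oxygen was set against the normal fetal ductus to ask which part of the birth response oxygen by itself brings. More probe sets were lower than higher in the oxygen ductus, 291 against 67 at 2-fold among 13789, or 81.3% lower. Higher genes were Bysl, needed for ribosome assembly (3.67-fold), Epor, the erythropoietin receptor (2.47-fold), Atp6v1h (2.47-fold), Prr14l (2.38-fold), Dbndd2 (2.34-fold), Ppp1r35 (2.26-fold), Vps37d (2.25-fold), Rabl6 (2.19-fold), Vcf1 (2.14-fold), Hpcal4 (2.08-fold), Aaas (at least 4.54-fold) and Commd7 (at least 2.78-fold). Lower genes were Tmem214 (4.31-fold), Cald1, caldesmon (3.15-fold), Tppp3 (3.09-fold), the tubulin Tuba1a (2.99-fold), Gask1b (2.92-fold), Tpp1 (2.90-fold), Mat2a (2.67-fold), Cd74, the class II invariant chain (2.61-fold), Hipk1 (2.58-fold), Ddx6 (2.55-fold) and Cyp2f4 (at least 3.53-fold). No list was above its random range. Lists below it were combined heart and skeletal muscle (-0.27, with Myl2 1.65-fold lower), immediate early (-0.18, with Ccn1 2.27-fold and Egr4 2.07-fold lower) and epithelial and cartilage genes (-0.40). Growth factor genes were below it too (-0.12, 1 at least 1.5-fold lower, Bmp4 at 2.06-fold, and 2 higher). Of 35 matrix genes (-0.04), 1 was at least 1.5-fold lower, Col6a1 (at least 2.45-fold), and 0 higher, with Sparc 1.49-fold lower. Of 23 hypoxia and glycolysis genes (-0.08), 3 were at least 1.5-fold lower and 0 higher, with Hk2 1.96-fold and Slc2a1 1.87-fold lower. Matched random lists were centred on 0.12 for matrix and 0.07 for hypoxia, so these 2 calls rest in part on that offset. The hypoxia call was lost with a lower floor and the epithelial call with a higher one. Probe sets from coding sequences read lower than tag probe sets of the same genes in this comparison (median log2 difference -0.35, 95% interval -0.52 to -0.19, 40 genes). This is as much as or more than most medians of the lists below their range, and the random lists were not matched on it.

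Smooth muscle genes were inside the random range in the oxygen ductus (0.19, 19 genes, 2 at least 1.5-fold higher and 1 lower). Des was 1.64-fold and Tpm2 1.57-fold higher, Cald1 was 3.15-fold lower, and Acta2 had a log2 ratio of -0.36. Endothelial (0.01), prostaglandin (0.04), vasoactive (0.05), channel (-0.09), glucocorticoid (-0.10), antioxidant (0.05), cell cycle (0.14), fatty acid (0.11), inflammatory (-0.27), leukocyte (-0.07), erythroid (0.05), nerve (-0.05) and fat (0.03) lists were inside the random range there too. Klf9 had a log2 ratio of 0.44, Atf3 of 0.15 and Fkbp5 of -0.24, where birth in the ductus gave 2.30, 1.74 and 1.88. The beta-actin control of the oxygen ductus had a 5' to 3' signal ratio of 0.346 (mean of 3 chips, SD 0.044), against means of 0.692 to 0.754 in the other 4 states. Of the same-gene partners of its 2-fold probe sets, 63.7% went the same way, and ratios of the same gene on different chips correlated with r = 0.085, against 0.298 to 0.519 in the other 5 comparisons. The single genes named for the oxygen ductus rest on 1 array each and on this weaker agreement.

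**Figure D4:**
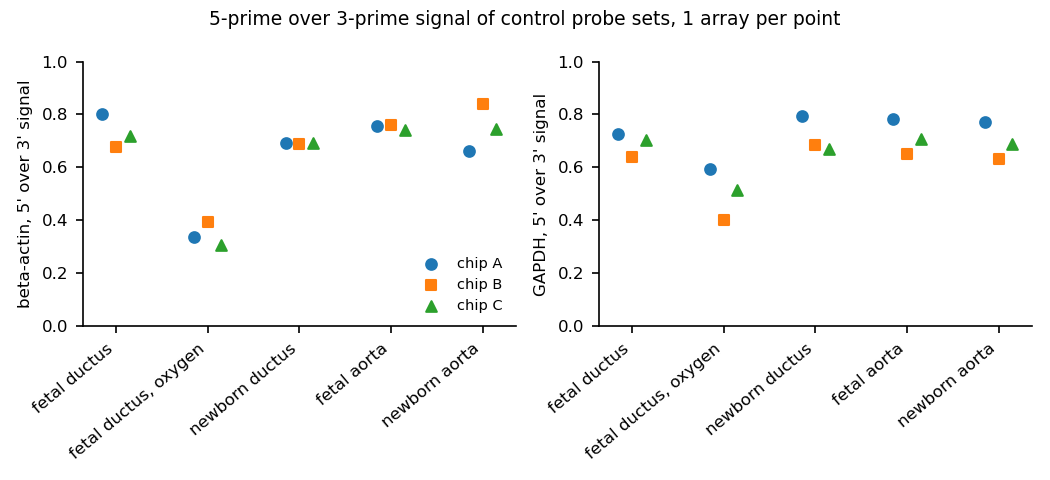
Ratio of 5' to 3' signal (y axis, no unit) of the beta-actin (left) and GAPDH (right) control probe sets in the 5 states (x axis), 1 point per array of chips A, B and C. The oxygen ductus has a beta-actin mean of 0.346, and the means of the other states over the 3 chips lie between 0.692 and 0.754.

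Oxygen and birth ratios in the ductus, both taken against the fetal ductus, were set side by side. Both were at least 2-fold higher in 12 probe sets, against 1.35 for independent lists, and both lower in 33, against 5.37, with 6 in opposite directions. Simulated unchanged arrays gave 0.46 and 0.69, with noise taken from the 4 arrays other than the oxygen ductus. They gave 19.5 probe sets at least 2-fold apart for oxygen against fetal ductus, where 358 were measured, so 0.46 and 0.69 may be too low. The 12 and 33 shared by oxygen and birth became 102 and 218 with a lower floor and 2 and 13 with a higher one. Dbndd2 (smaller fold of the 2 ratios 2.34), RT1-A1 (1.99), the platelet chemokine Pf4 (1.96), Prr14l (1.93), Tomm40 (1.92), Ecm1 (1.87), Mthfd2 (1.83), RGD1309362 (1.81), Ramp1 (1.75) and Plac9 (1.67) were higher in both. Cd74 (2.61), Nudcd2 (2.30), Appl2 (1.91), Ldb2 (1.86), Abhd11 (1.83), Itgb1bp2 (1.83), Zfp507 (1.82), Sap30 (1.81), Ccnh (1.73) and Abhd17c (1.72) were lower in both. The correlation was 0.18 across 14536 probe sets, where unchanged arrays sharing the fetal ductus gave 0.50, and the covariance was 0.0319 against 0.0439. The value of 0.50 follows from sharing an array at equal noise. Real changes that differ between the 2 comparisons lower r, so an r under 0.50 cannot tell whether they share a response. The simulated covariance rests on noise from the interaction contrast, which may hold real differences and so be too large. Some or all of the overlap may come from the shared fetal array, and these values do not settle it. Against the birth ratios of the aorta, which share no array, r was 0.059, with 8 probe sets higher in both (1.62 for independent lists), 18 lower in both (6.96) and 15 in opposite directions. Of the 1040 at least 2-fold apart in either, 48.4% had the same sign in both.

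Newborn and oxygen ductus differed more than the vessels of any other of the 6 comparisons, with 639 probe sets at least 2-fold higher and 380 lower in the newborn among 14007. Glucocorticoid-responsive (0.97, 16 genes) and immediate early genes (0.85, 28 genes) were higher in the newborn, with Fkbp5 4.35-fold, Klf2 4.25-fold, Errfi1 3.90-fold, Glul 3.83-fold and Pdk4 at least 3.16-fold. Endothelial (0.69), leukocyte (0.46), vasoactive (0.45), matrix (0.33), smooth muscle (0.28), erythroid (0.38, mean -0.12, 4 genes at least 1.5-fold higher and 3 lower, a call lost with quantile normalization) and growth factor genes (0.12, lost with a higher floor) were above their random ranges. Other higher genes were Alox15 (4.54-fold), Tppp3 (4.39-fold), Bnip3 (4.21-fold), Hist1h2bq (4.14-fold), Ltbp2 (4.06-fold), Nupr1 (3.82-fold), Car3 (at least 3.90-fold), Hip1r (at least 3.69-fold), Kcnd3 (at least 3.32-fold) and Adgrg6 (at least 2.96-fold). Cell cycle genes (-0.82, 29 genes, 21 at least 1.5-fold lower) and the combined heart and skeletal muscle list (-0.57, heart genes -1.15, skeletal genes 0.14) were lower. Lower single genes were Hbe1 (24.8-fold), Cenpn (4.45-fold), Tnnt2 (4.33-fold), Slc22a17 (3.99-fold), Wdr24 (3.91-fold), Zfp266 (3.87-fold), Polr3d (3.45-fold), Myl2 (3.44-fold), Cdca7 (3.34-fold), Myl7 (3.15-fold), Bysl (at least 4.38-fold), Ppp1r35 (at least 2.99-fold), Hbz (at least 2.94-fold), Rpp25l (at least 2.65-fold) and Oas1a (at least 2.62-fold). Prostaglandin (0.04), channel (0.06), hypoxia (-0.08), antioxidant (0.05), fatty acid (-0.13), inflammatory (0.32), nerve (0.13), fat (0.36) and epithelial (0.06) lists were inside the random range. The low 5' control signal of the oxygen ductus enters this comparison too, where coding-sequence probe sets read higher than tag probe sets of the same genes by a median of 0.48 (38 genes).

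Markers of single states, at least 2-fold above each of the other 3 normal states, were fewest for the fetal ductus (18 probe sets, 8 named genes) and most numerous for the newborn aorta (52, 28 genes). The fetal ductus was marked by Myl3 (at least 3.36-fold above the next state), Myl2 (3.32-fold), Myh7 (2.35-fold), the cartilage collagen Col9a1 (2.17-fold) and Fabp3 (2.08-fold). The newborn ductus had 33 such probe sets (14 genes), led by Fkbp5 (3.15-fold), Gal (3.00-fold), Phf1 (at least 2.69-fold), Emp1 (2.47-fold) and Adamts1 (2.37-fold). The fetal aorta had 27 (18 genes), led by Gas2 (4.21-fold), Alb (at least 3.32-fold), Hbz (2.75-fold), Hbe1 (2.57-fold) and Th (2.53-fold). The newborn aorta was marked by Car3 (15.6-fold), Gpd1 (at least 13.4-fold), Fabp4 (12.0-fold), Pck1 (at least 7.53-fold) and Ucp1 (at least 5.85-fold). The fetal ductus markers thus held heart muscle genes (Myl2, Myl3, Myh7) and the newborn aorta markers fat genes (Fabp4, Ucp1).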

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

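The tests of fat and heart muscle cells given here were chosen after the values were seen, and those of the oxygen ductus were written down before their results.

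Fat genes stood out in the newborn aorta, by a median log2 ratio of 1.59 over the fetal aorta. If fat cells on that sample were the cause, most fat genes should be highest there, and 63.64% (7 of 11 measured) were at least 1.5-fold above every other state, between the limits set for and against. Signals there were 3489 for Fabp4, 1770 for Dgat2, 1343 for Pparg, 1339 for Cidea and 1075 for Adipoq, on different chips, so they do not rank abundance. Lep, Lipe, Scd and Dgat1 were under 1.5-fold. On these arrays the fat genes did not reach the same level in both newborn vessels, with a median of -1.9844 in the newborn ductus over the newborn aorta (8 of 10 genes at least 1.5-fold lower). This value was known when the test of an equal birth response was chosen, so it restates the pattern. A smaller birth response in the ductus was left open by its median of 0.3349 with birth, over the 6 genes above the floor there. Fat cells left on the newborn aorta, although the labels say the vessels were cleaned, may explain the pattern, and cannot be told apart from a response of the aorta itself because 1 array per chip holds that state.

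Heart muscle genes were high in the fetal ductus, and the combined list of heart and skeletal muscle genes had a median of 0.675 for ductus over aorta in the fetus and -0.472 in the newborn, and of -0.575 with birth in the ductus and 0.354 in the aorta, opposite directions whose difference was not tested. Split after these values were seen, 14 heart muscle genes had a median of 1.06 in the fetal ductus over the fetal aorta and 6 skeletal muscle genes one of -0.47. Heart muscle cells on the fetal ductus were left open: 64.29% (9 of 14) of the heart genes were at least 1.5-fold above both the fetal aorta and the newborn ductus, between the limits, a share that partly restates the values that prompted the split, and Nppa, at 630 in the fetal and 435 in the newborn ductus, was lower by less than Myl2 or Tnnt2. The oxygen ductus, a separate sample, held the heart genes too, with a median of -0.20 against the fetal ductus and of -1.15 for the newborn against it. A fall of all muscle genes with birth was argued against by the smooth muscle median of 0.5254 in the opposite direction, a value seen before this test was chosen. A change of heart genes within the ductus stays open.

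The oxygen ductus had a beta-actin 5' to 3' ratio of 0.3463, from control probe sets that no comparison used, the lowest of the 5 states, and a GAPDH ratio of 0.503 against 0.690 to 0.716 (means of 3 chips). If loss of 5' signal lowered its values, probe sets from coding sequences should be lower than those from expressed sequence tags of the same gene. Their median difference against the fetal ductus was -0.3537 (40 genes, 95% interval -0.52 to -0.19, 30 negative), against -0.07 to 0.15 in the 4 comparisons without the oxygen ductus. Among those 4, the interval also excluded 0, on the positive side, for newborn over fetal ductus (0.055 to 0.283) and newborn ductus over aorta (0.017 to 0.147). An unequal distribution of signals was argued against, because 75.56% of the 2-fold probe sets were still lower after quantile normalization. Degraded or shorter labelled RNA may thus be part of the excess of lower probe sets. The share lower was 88.7% on chip A and 73.5% and 82.0% on chips B and C, which carry mostly tag sequences. The beta-actin ratio was low on all 3 chips (0.339, 0.393 and 0.307), so these shares cannot tell whether such RNA is all of the cause. A response to oxygen stays open, untested apart from this.

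Leukocyte genes had a median of 0.442 with birth in the ductus and -0.332 in the aorta, opposite directions whose difference was not tested. The 5S ribosomal RNA control signal was highest in the newborn ductus, at 4606 (mean of 3 chips) against 878 to 2266 in the other states, outside the comparisons made.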

How the results depend on the processing

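Leaving out genes of the fat, fatty acid, heart and skeletal muscle, erythroid, nerve, leukocyte and epithelial lists was a test chosen after the data were seen. The floor sets how many probe sets are compared and how far a dim one can move, and it moved the counts of the 6 pairs by more than 1.5 times, which neither scaling did. With the floor at the 25th and then the 65th percentile, probe sets 2-fold higher and lower were 602 and 618, then 81 and 64, for ductus over aorta in the fetus; 732 and 752, then 92 and 86, in the newborn; 838 and 918, then 178 and 120, with birth in the ductus; and 933 and 1096, then 210 and 171, with birth in the aorta. For the oxygen over the fetal ductus they were 326 and 1128, then 26 and 132, and for the newborn over the oxygen ductus 1751 and 898, then 349 and 204. The interaction contrast gave 372 and 21. The birth responses of both vessels correlated with r = 0.2937 at the lower floor, with 187 probe sets higher in both and 198 lower in both (33 lower at the higher floor). Oxygen and birth shared 102 higher and 218 lower probe sets, then 2 and 13.

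By limma the vessel effect had 22 probe sets past the threshold with quantile normalization (4 of the 5 among them), 0 at the lower floor (1383 unadjusted, lowest adjusted p 0.149), 9 at the higher floor, 64 with an intensity trend and 1 with the oxygen ductus added. The birth effect had 0 by limma at the lower floor (2714 unadjusted, lowest adjusted p 0.0848), 534 with the trend (221 of the 228 among them), 3 with the oxygen ductus added (2278 unadjusted), 283 with quantile normalization (61 shared) and 303 at the higher floor (157 shared). All 228 kept their direction in each setting, apart from 7 that were not among those tested at the higher floor. Why the calls changed was not tested.

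Of 120 list results, 3 turned direction: vasoactive genes with birth in the aorta (-0.0077) and channels in the fetal ductus over the aorta (-0.0922) at the lower floor, and epithelial genes in the fetal ductus over the aorta (-0.0212) at the higher. The others kept direction, with 11 losing and 27 gaining their place outside the random range over all settings, and 557 unchanged. Unscaled values changed no list call and gave 5 vessel and 233 birth probe sets past limma. Of 168 named gene ratios, 49 moved when all probe sets of a gene were averaged and 0 with either other scaling. The counts without the other-tissue lists stayed within 1.5 times in all 14 results, with 5 vessel and 208 birth probe sets past limma. Only the listed genes are removed by this setting, and others such as Car3 and Gpd1 stay in, so it cannot tell whether other tissue affected the counts. Leaving out an array could not be done, as each state had 1 per chip and the fit would keep 0 residual degrees of freedom.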

Other observations

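Sterol synthesis genes were lower after birth in both vessels. The tests of a sterol list and of a circadian list were written down after single genes of each group (Sqle and Msmo1, and Per2) had been seen, on members whose values had not been looked at, and they were the 2 lists tried in this way. The sterol median was -0.4959 in the ductus (13 genes, percentile 0.04 of random lists) and -0.6921 in the aorta (12 genes, percentile 0). These members were read on the same arrays as the genes that prompted the list and may vary together with them. The percentiles may therefore overstate the support. In the ductus Sc5d was 2.02-fold, Cyp51 1.98-fold and Nsdhl 1.93-fold lower, and in the aorta Tm7sf2 2.82-fold, the regulator Srebf2 1.92-fold and Cyp51 1.83-fold. Lower sterol synthesis after birth may be one part of the shared response, and its link to feeding, age or hormones was not tested. The same list was at -0.16 in the fetal and -0.26 in the newborn ductus over the aorta, -0.16 in the oxygen over the fetal ductus and -0.55 in the newborn over the oxygen ductus.

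Circadian clock genes had a median of 0.485 with birth in the ductus (5 genes, percentile 99.3), with Nr1d1 1.51-fold and Tef 1.40-fold higher. In the aorta fewer than 5 were measured, so the group was left open, and the time of day of sampling is not in the labels. The median was 0.22 in the newborn ductus over the aorta and 0.08 over the oxygen ductus.

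Split from the list of heart and skeletal muscle after its values were seen, heart genes had medians of -0.72 in the newborn ductus over the aorta, -1.14 with birth in the ductus, 0.58 with birth in the aorta, -0.20 in the oxygen over the fetal ductus and -1.15 in the newborn over the oxygen ductus. Skeletal genes had 0.00, -0.12, -0.18, -0.34 and 0.14. Among all 10 pairs of states the number of 2-fold probe sets ran from 273 (fetal ductus and aorta) to 1132 (oxygen ductus and newborn aorta). The 3 pairs with the oxygen ductus other than that with the fetal ductus had 721, 1019 and 1132.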
